A study of Homo sapiens with 12 samples.

How the data were processed

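The arrays were Illumina BeadChips hybridised with biotin-labelled cRNA made from 3000 ng of total RNA of U937 cells, per the labels' protocols. Groups came from the treatment given for each sample, with 4 control, 4 EX527 and 4 MC2494 arrays, and no column of sample values was left unused. The deposited signal table holds each probe's average bead intensity on a linear scale, not background-subtracted and not normalized between arrays, as its values show. Beside each intensity the deposited table gives a detection p-value, per the file headers, which within each of the 12 arrays never rose with rising intensity. A further deposited table holds log2 values that the authors made. Its 12 columns share the same sorted values within 0.001, so it had been quantile normalized, and the order of probes in each column is that of the intensity column of the same sample. The submitters' processing notes name limma. The scanner software, the background correction behind the deposited log2 values and the source of their common distribution, which lies up to 0.041 from the mean sorted log2 intensity, are not given in the sources used here. The median of each of these log2 columns was 6.4368.

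Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which infers the background from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. Quantile normalization gives all arrays one distribution, so a difference in total signal between groups is removed and each change is relative to the other genes. Of 24526 probes, 21834 carried 1 gene symbol in the platform annotation, 0 carried several and 2692 carried none. Symbols were checked through Entrez identifiers against a RefSeq gene table of GRCh38.p14, which was used for names only, and 21 named probes had no entry there and kept their older symbol. Probes with a detection p under 0.05 in at least 4 of the 12 arrays were kept, which left 13174, of which 11959 were named. Each gene was represented by its kept probe with the highest mean, giving 9956 genes, 1579 of them with a choice of probes. Where another kept probe of a gene named in the text pointed the other way or differed widely, its value is given. No genome build is named with the arrays, so no coordinates are given. A gene not detected on any of the 4 arrays of a group has only a bound there, and its fold is written "at least", from the brighter group's mean against the higher of the dim probe's signal and the lowest detected signal per array.

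A linear model with a mean per group was fitted to all 12 arrays with lmFit and eBayes, so that the groups share one estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The median spread within groups was 0.1 on the log2 scale. Standard errors of log2 fold changes are from that model. Mean signals were compared by exact permutation tests. The 31 gene lists were fixed before the data were examined, and the 28 with at least 5 measured genes were tested with camera of limma, 2-sided, at a preset correlation of 0.01 and again with an estimated correlation. A gene or list past the threshold is written as called. Members of a list were counted at adjusted p under 0.05 over all genes and adjusted over the list alone. The main tests, the lists and the alternatives were chosen before the data were examined except where stated.

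Genes were named by a rule set at the same time. Per comparison it takes the 8 largest rises and 8 largest falls among genes past the threshold with non-overlapping groups and an informative symbol, the 3 most changed members of each list with at least 3 changed members, and the sirtuin genes SIRT1 to SIRT7, and the text gives part of these 292 results. Where 5 or fewer members of a list moved against the others or did not pass, and where a gene's value is set beside another comparison, the genes named were chosen after their values were seen.

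The procedure was tested on simulated data for the same 9956 genes with known changes. Simulated changes of 0.5 on the log2 scale were called with the right sign for 88.06% of genes in MC2494 against control, 86.57% in EX527 against control and 86.57% in MC2494 against EX527. Changes of 2 were called in 100% in each. Unchanged genes made up 3.636%, 5.804% and 4.018% of calls, and 0 of 20 unshifted lists were called in each comparison. In each simulation 225 of 9956 genes changed, far fewer than were called in the real arrays. Its noise was independent between genes, unlike genes that vary together. These rates need not hold for the real arrays. Comparisons against the same controls were set beside 1000 simulations of groups without effect for correlation and covariance.

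Alternatives changed the background correction, offset, scaling, detection filter, probe choice, variance model, array weights, threshold, samples in the fit and replicate block, left out each array in turn, and used the authors' deposited log2 values. Probes without a gene symbol were not used in the comparisons.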

Results

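Gene expression was measured in U937, a human leukaemia cell line of monocytic character, on 12 bead arrays. Cells had been left as controls or exposed for 24 h to EX527, an inhibitor of the NAD-dependent deacetylase SIRT1, or to MC2494, which the series introduces as a sirtuin inhibitor. Each of the 3 groups held 4 arrays. The labels give no dose for either compound and do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between arrays, which may be technical. Mean raw signal was 779.3 ± 14.5 in control, 736.2 ± 32.3 in EX527 and 662.8 ± 31 in MC2494 (SD, n = 4 arrays). The MC2494 arrays were dimmer than the controls (2-sided exact permutation test, p = 0.0286, the smallest that 4 arrays against 4 can give), and for EX527 the exact p was 0.0857. Between 12231 and 13030 of 24526 probes were detected per array. After normalization, 9956 genes were tested, and the number of arrays limits the precision of each value.

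The 3 groups stood apart on the first 2 principal components, which held 70.3% and 18.8% of the variance over the genes tested.

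**Figure D1:**
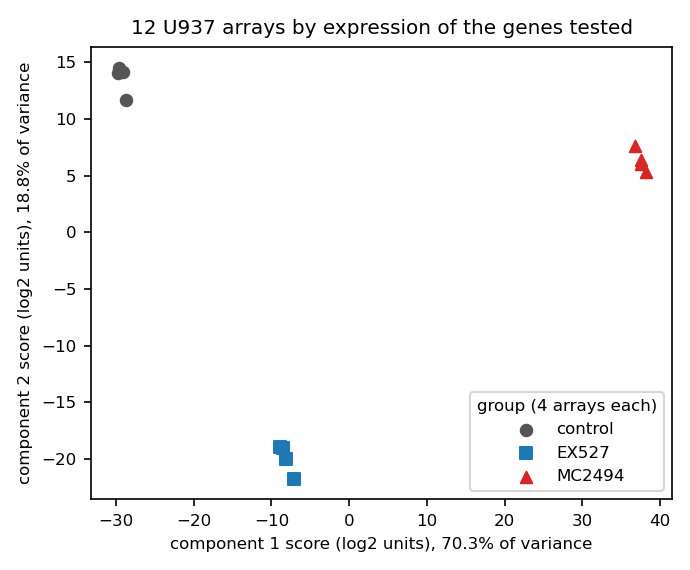
Scores of the 12 arrays on the first 2 principal components of the normalized log2 values of the genes tested, 1 point per array, with the share of variance on each axis. Component 1 (70.3%) places control arrays at -29.8 to -28.75 and MC2494 arrays at 36.77 to 38.13, and component 2 (18.8%) places EX527 arrays at -21.73 to -18.95, below both other groups.

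The first comparison asked which transcripts differed between cells given MC2494 and control cells. Genes of cell division fell together: all 30 measured genes of mitosis and 28 of 29 measured genes of DNA replication were lower. Genes of the amino acid response, which the transcription factors ATF4 and CHOP switch on when amino acids run short or unfolded proteins build up, rose in 23 of 25 cases. The largest single rise was that of NUPR1, a stress-induced nuclear protein of that list, at 23.1-fold (log2 fold change 4.53 ± 0.06, SE, n = 4 arrays per group; limma adjusted p = 3.1e-15). The largest fall was that of the collagenase gene MMP1, at 8.99-fold (log2 fold change -3.17 ± 0.10, limma adjusted p = 4.4e-12), detected on 3 of the 4 MC2494 arrays.

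Among the other large rises in MC2494, MFAP4, an extracellular matrix glycoprotein, was 13.1-fold higher, and PLIN2, a coat protein of lipid droplets, was 9.79-fold higher. VWA5A was 9.34-fold higher, and PPARGC1A, a coactivator of mitochondrial and oxidative genes, was 8.29-fold higher. DDIT4, an inhibitor of mTORC1 signalling, was 7.39-fold higher, and OSCAR, an immunoglobulin-like receptor of myeloid cells, was 7.13-fold higher. The water channel gene AQP8 was not detected on any control array and was at least 6.98-fold higher in MC2494. On the falling side, CDCA3, which takes part in entry into mitosis, was 8.16-fold lower. ARHGEF39 was 7.44-fold lower (-1.97 on the log2 scale on another probe), and the kinetochore component SPC25, detected on 1 of the 4 MC2494 arrays, was 7.36-fold lower by fitted values and 7.12-fold with the undetected arrays at the lowest detected signal. The mitotic kinesin KIF20A was 7.25-fold lower, the cytidine deaminase APOBEC3B was 7.22-fold lower, ART3 was 6.87-fold lower and the collagen gene COL22A1, detected on 1 of the 4 MC2494 arrays, was 6.41-fold lower, or 5.91-fold in that way. Adjusted p from limma lay at or below 2.5e-11 for each of these genes.

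The mitosis list fell with a median log2 change of -1.61 (limma camera, adjusted p = 7.4e-15). KIF20A led it, followed by the cyclin CCNA2 and the proliferation marker MKI67, each 4.9-fold lower. The DNA replication list fell with a median of -1.52 (adjusted p = 2e-13). RRM2, a subunit of ribonucleotide reductase, fell by 2.32 on the log2 scale, the thymidine kinase TK1 fell by 2.19 and the thymidylate synthase TYMS fell by 2.15. SLBP, at -0.32, was the member of that list that missed the threshold. Of 11 measured genes of homologous recombination and Fanconi repair, 9 fell and 2 rose, with a median of -0.95 (adjusted p = 0.0044). RAD54L fell by 2.11, FANCG by 1.55 and EXO1 by 1.51, while PALB2 (0.61) and XRCC2 (0.39) rose. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was 4.39-fold higher. A further CDKN1A probe gave a log2 fold change of 0.24.

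In the amino acid response list the median log2 change was 0.88 (limma camera, adjusted p = 3.1e-08), or 0.76 with 1 member not detected in control at its bound. DDIT4 and DDIT3, the gene of CHOP, stood behind NUPR1, and DDIT3 rose by 2.41 ± 0.06 (SE). PCK2 (-0.20) fell, and CHAC1 (-0.20) did not pass the test. Ribosome biogenesis genes fell in 24 of 27 cases with a median of -0.53 (adjusted p = 2.9e-06), which was -0.85 with median scaling and with no scaling. NOLC1 fell by 1.54, MYBBP1A by 1.26 and NOP16 by 1.00, and NOP58 (0.61) rose. These lists and the 3 of cell division and repair held with an estimated correlation between genes.

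For the 3 other lists called in this comparison the call was lost with an estimated correlation. Of 14 measured NRF2 antioxidant targets, 9 rose and 2 fell, with a median of 0.64 (camera adjusted p = 0.013, and adjusted p = 0.12 with an estimated correlation). That median was 0.46 with 1 member not detected in control at its bound and 0.21 with no filter on detection. The haem oxygenase HMOX1 was 3.32-fold higher, SRXN1 2.31-fold and NQO1 2.1-fold, whereas PRDX1 (-0.54) and GSR (-0.30) fell. Of 14 measured NF-kappaB and inflammatory genes, 11 fell and 2 rose, with a median of -0.44 (adjusted p = 0.02, and adjusted p = 0.096 with an estimated correlation). The chemokine genes CCL2 and CXCL8 were 4.28-fold and 2.3-fold lower, TNF was 2.51-fold lower, and PTGS2 (0.82) and TNFAIP3 (0.39) rose. Of 29 measured genes of cytosolic ribosomal proteins, 21 rose and 1 fell, with a median of 0.32 (adjusted p = 0.0027, and adjusted p = 0.051 with an estimated correlation). RPS23 rose by 1.10, RPS7 fell by 1.86, and RPL14 rose by 1.07 on its brightest probe with -0.47 on another. With median scaling in place of quantile normalization, or with no scaling between arrays, these 3 lists kept their direction and lost their call, at adjusted p of up to 0.084, 0.081 and 0.11. Their medians were 0.37, -0.50 and 0.10 with median scaling and 0.36, -0.51 and 0.09 with no scaling.

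Several other lists were not called as a whole. Of 5 measured sirtuin genes, SIRT2 was 2.11-fold higher (log2 fold change 1.08 ± 0.06), SIRT1 2.04-fold, SIRT5 1.51-fold and SIRT4 1.31-fold, and the list as a whole was not called (camera adjusted p = 0.14). Other probes of SIRT5 gave log2 fold changes of 1.72 and 0.79. SIRT6 was lower by -0.28 ± 0.10 (limma adjusted p = 0.017). That call was lost without control replicate 3, control replicate 4 or MC2494 replicate 1, with changes of -0.24, -0.23 and -0.20 and adjusted p of 0.052, 0.057 and 0.063. It was also lost in replicates 1 and 2 alone, at -0.16 (adjusted p = 0.36). SIRT3 and SIRT7 had no named probe above the detection filter. Of 18 measured genes of monocyte and macrophage differentiation, 8 rose and 9 fell (adjusted p = 0.63), among them falls of the lysozyme gene LYZ (3.55-fold), FCN1 (3.21-fold) and S100A9 (2.95-fold). Of 19 measured p53 targets, 11 rose and 4 fell (adjusted p = 0.14), with GDF15, detected on 2 of 4 control arrays, at 3.98-fold and PMAIP1, a pro-apoptotic BCL2 family member, at 2.7-fold. In the death receptor list 7 of 15 rose and 3 fell (adjusted p = 0.55). BIRC2 was 2.91-fold higher, TNFRSF10D, detected on 1 of 4 control arrays, 2.17-fold (1.87-fold with the undetected arrays at the lowest detected signal) and the TRAIL receptor gene TNFRSF10B 1.81-fold, its other probes giving 0.35 and -0.19 on the log2 scale. Among BCL2 family genes 8 rose and 6 fell, with a median of -0.01, a mean of 0.18 and a test pointing upward (camera adjusted p = 0.63). BMF, detected on 2 of 4 control arrays, rose 2.35-fold and BCL2L11 fell 2.96-fold. Other BCL2L11 probes gave -1.53 and -0.97 on the log2 scale.

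In all, 7222 of 9956 genes passed an adjusted p of 0.05 for MC2494 against control (limma), 3733 higher and 3489 lower. The share of higher genes, 51.7%, was 43.1% with median scaling and 42.5% with no scaling. At least 2-fold differed 1217 genes (648 higher and 569 lower), those not detected in the dimmer group taken at their bound. The 4 values of each group did not overlap for 65.7% of genes, against 2.86% by chance. Of 28 lists tested 8 were called, 5 with an estimated correlation. Counts of changed members adjusted over the list alone equalled those over all genes for the lists called, except ribosome biogenesis (26 against 25).

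**Figure D2:**
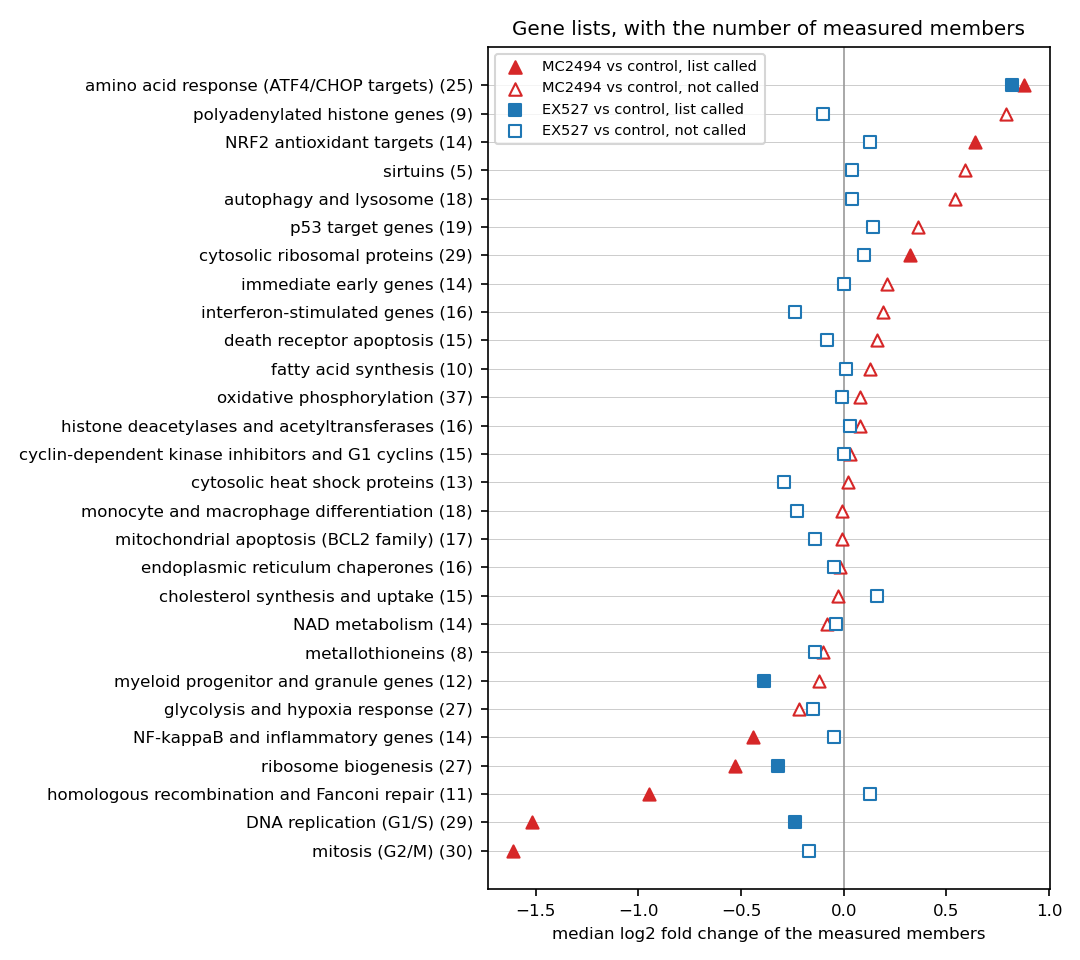
Median log2 fold change against control of the measured members of each of the 28 gene lists tested, as triangles for MC2494 and squares for EX527, filled where the list was called by camera with the preset correlation. The mitosis list lies at -1.61 in MC2494 and -0.17 in EX527, and the amino acid response list at 0.88 and 0.82; the filled MC2494 symbols of the NRF2, NF-kappaB and ribosomal protein lists lost their call with an estimated correlation and with median or no scaling.

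The next comparison asked which transcripts differed after EX527. The largest rise was that of the lipid droplet gene PLIN2, at 11.8-fold (log2 fold change 3.56 ± 0.05, SE, n = 4 arrays per group; limma adjusted p = 2.3e-14). Amino acid response genes rose in 23 of 25 cases, and DNA replication genes fell in 20 of 29. The largest fall was that of the collagen gene COL22A1, at 5.39-fold (log2 fold change -2.43 ± 0.10, limma adjusted p = 7.8e-10), detected on 3 of the 4 EX527 arrays.

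CREB3L3, a transcription factor of lipid metabolism, was not detected on any control array and was at least 4.68-fold higher in EX527. VWA5A was 5.3-fold higher, with 1.34 on the log2 scale on another probe. CYP1A1, a cytochrome P450 enzyme and a standard target of the aryl hydrocarbon receptor, was 4.58-fold higher (log2 fold change 2.19 ± 0.07). CCPG1 was 4.28-fold higher, and the fatty acid binding protein gene FABP4, not detected on any control array, was at least 2.8-fold higher. Of the genes that fell, RASL11A was 3.66-fold lower, and CEP70, a centrosomal protein gene not detected on any EX527 array, was at least 2.26-fold lower. IFIT2 and IFIT1, both interferon-induced, were 3.04-fold and 2.93-fold lower, detected on 1 and 2 of the 4 EX527 arrays. With the undetected arrays at the lowest detected signal these falls were 2.86-fold and 2.85-fold. The B cell receptor component CD79A was 3.01-fold lower, and GPR84 and SSH3 were each 2.84-fold lower. Adjusted p from limma lay at or below 1.1e-08 for each of these genes.

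The amino acid response list rose with a median log2 change of 0.82 (limma camera, adjusted p = 2.3e-14), or 0.79 with 1 member not detected in control at its bound. ASNS, the asparagine synthetase, was 4.4-fold higher, DDIT4 4.04-fold and NUPR1 3.35-fold, and CHAC1 (-0.24) and CEBPB (0.04) did not pass the test. The DNA replication list fell with a median of -0.24 (adjusted p = 0.00027), led by MCM2, GINS2 and ORC1, which fell by 0.75, 0.69 and 0.62. Of 27 measured ribosome biogenesis genes 20 fell and 1 rose, with a median of -0.32 (adjusted p = 0.00027), NOP58 rising by 0.79, RRP9 falling by 0.66 and NOP16 by 0.62. Of 12 measured genes of myeloid progenitors and granules 8 fell and none rose, with a median of -0.39 (adjusted p = 0.0043), which was -0.20 with no filter on detection. The proteinase gene PRTN3 was 2.02-fold lower, RNASE2 1.76-fold and AZU1 1.49-fold, and MYB, MYC, CTSG and GFI1 did not pass the test. These 4 lists were the ones called of 28, and the calls held with an estimated correlation.

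The mitosis list split in EX527: 11 of 30 genes rose, 15 fell and 4 did not pass, with a median of -0.17, a mean of 0.04, a test pointing downward and no call (camera adjusted p = 0.88). HMMR was 2.45-fold higher, the topoisomerase TOP2A 1.97-fold and the kinetochore motor CENPE 1.95-fold. Repair genes likewise were not called (adjusted p = 0.26), with RAD51AP1 at 2.16-fold and BRCA1 at 1.74-fold higher. CDKN1A was 2.02-fold higher, with 0.37 on the log2 scale on another probe. Of the sirtuins, SIRT1 was 1.51-fold higher (log2 fold change 0.59 ± 0.07, limma adjusted p = 4.3e-06) and SIRT4 was lower by -0.39 ± 0.09 (adjusted p = 0.0017), a call lost in replicates 1 and 2 alone (-0.27, adjusted p = 0.052). SIRT2 at 0.04 ± 0.06, SIRT5 at 0.13 ± 0.06 and SIRT6 at -0.12 ± 0.10 did not pass, and other SIRT5 probes gave 0.76 and 0.31. Among monocyte and macrophage genes 6 rose and 10 fell (camera adjusted p = 0.34), with CD86, detected on 1 of 4 control arrays, at 2.05-fold higher (1.9-fold with the undetected arrays at the lowest detected signal, and 0.26 on the log2 scale on another probe) and CSF1R, the receptor for macrophage colony-stimulating factor, at 2.03-fold lower. GDF15, the stress-induced cytokine gene, was 3.67-fold higher and HMOX1 was 2.54-fold higher. Their lists were not called (camera adjusted p = 0.16 for p53 targets and 0.14 for NRF2 targets). GDF15 was detected on 2 of 4 control arrays, and its rise was 3.5-fold with the undetected arrays at the lowest detected signal.

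For EX527 against control 5656 of 9956 genes passed (limma), 2574 higher and 3082 lower, and 247 differed at least 2-fold (202 higher and 45 lower) with undetected genes at their bound. The 4 values of each group did not overlap for 51.6% of genes, against 2.86% by chance. Counts adjusted over the list alone equalled those over all genes for the 4 lists called. Markers of other cell types were few in both comparisons with control. Of 15 lymphocyte markers 4 were measured, of 15 erythroid and megakaryocyte markers 4, and of 14 epithelial and fibroblast markers 2, too few to test. CD79A was lower in MC2494 as well, at -1.70.

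**Figure D3:**
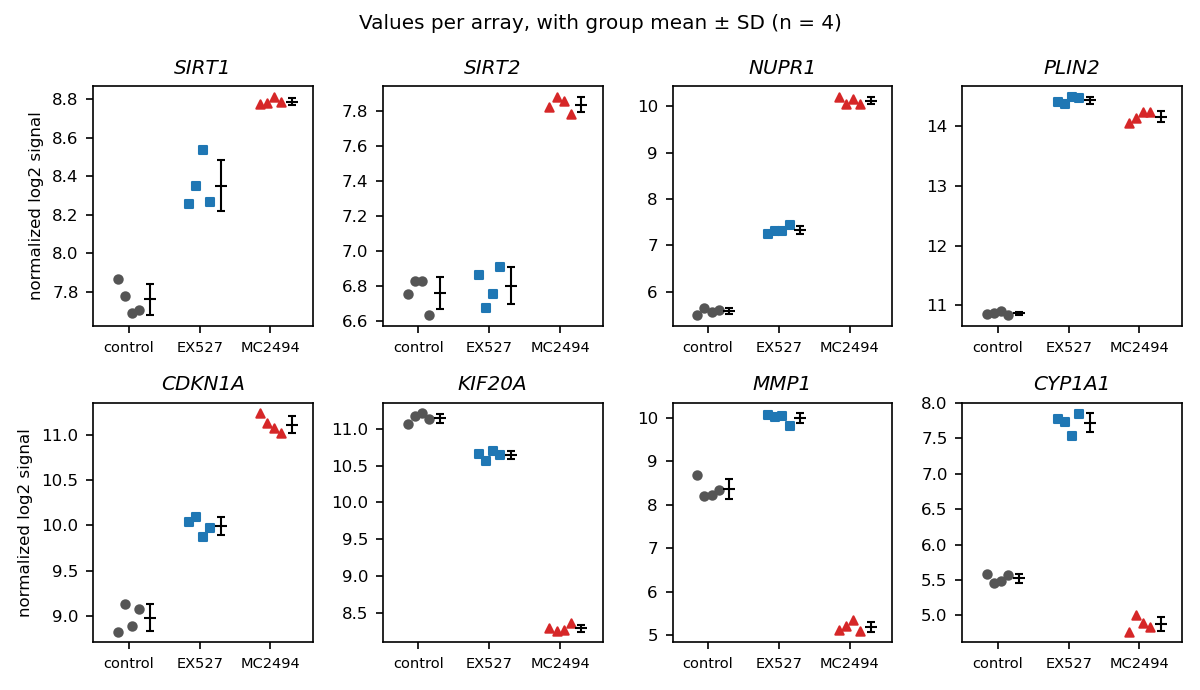
Normalized log2 signal of 8 genes on each array, 1 point per array in control, EX527 and MC2494, with group mean and SD (n = 4) to the right of the points; vertical axes differ between panels and do not start at 0. MMP1 averaged 8.37 in control, 9.99 in EX527 and 5.2 in MC2494, and CYP1A1 5.52, 7.72 and, not detected, 4.88, whereas PLIN2 averaged 10.87, 14.43 and 14.16.

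The third comparison set MC2494 directly against EX527, at doses that are not given and may differ. The 30 measured mitosis genes were all lower in MC2494, with a median of -1.72 (limma camera, adjusted p = 5.5e-21). MMP1 was 27.6-fold lower in MC2494 (log2 difference -4.78 ± 0.10, SE, n = 4 arrays per group; limma adjusted p = 7.6e-13). The chemokine receptor gene CX3CR1 was 9.91-fold higher (log2 difference 3.31 ± 0.09, limma adjusted p = 3e-12). MFAP4 was 8.63-fold and NUPR1 6.9-fold higher.

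Other genes that were higher in MC2494 included the potassium channel subunit KCNE1 (5.42-fold), CYSRT1 (5.29-fold, detected on 2 of the 4 EX527 arrays) and the forkhead factor FOXP4 (5.27-fold), with 1.08 on the log2 scale on another FOXP4 probe. ZMYND15, not detected on any EX527 array, was at least 4.33-fold higher. LHX3 was 5.01-fold higher on its brightest probe and differed by 0.06 on the log2 scale on another. KCNE1 and LHX3 were each detected on 3 of the 4 EX527 arrays. With the undetected arrays at the lowest detected signal they were 5.24-fold and 4.91-fold higher. CYP1A1 and the neutrophil collagenase gene MMP8 were not detected on any MC2494 array and were at least 6.03-fold and 3.42-fold lower there. CDCA3 was 5.74-fold lower, the oxysterol receptor gene GPR183 5.65-fold and APOBEC3B 5.41-fold. Adjusted p from limma lay at or below 4e-09 for each of these genes.

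In the lists, DNA replication genes were lower in MC2494 in 27 of 29 cases with a median of -1.05 (camera adjusted p = 2.8e-14), RRM2 by 4.84-fold, TYMS by 3.94-fold and CDC45 by 3.55-fold; UNG (0.26) was higher. Repair genes were lower in 8 of 11 with a median of -1.35 (adjusted p = 6.8e-05), with RAD54L at 4.07-fold, RAD51AP1 at 3.63-fold and BRCA1 at 3.32-fold, and XRCC2 (0.26) was higher. Ribosome biogenesis genes were lower in 16 of 27 and higher in 2, with a median of -0.26 (adjusted p = 0.0013), which was -0.44 with no scaling. NOLC1 was 2.13-fold lower, and RRP9 (0.42) and PNO1 (0.22) were higher. These 4 lists held with an estimated correlation.

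Interferon-stimulated genes were higher in MC2494 than in EX527 in 11 of 16 cases and lower in 2, with a median of 0.60 (camera adjusted p = 0.0052, and adjusted p = 0.065 with an estimated correlation), which was 0.32 with no filter on detection. IFIT1 was 4.45-fold higher, IFIT2 2.47-fold and XAF1 2.11-fold, and HERC5 (-0.53) and MX2 (-0.30) were lower. With the undetected EX527 arrays at the lowest detected signal, IFIT1 was 4.33-fold and IFIT2 2.32-fold higher. Against control, this list was not called in either compound (camera adjusted p = 0.32 in MC2494 and 0.17 in EX527). IFIT1 was higher in MC2494 than in control by 0.60 and lower in EX527 by -1.55. Polyadenylated histone genes were higher in 6 of 9, with a median of 0.74 (adjusted p = 0.016, and adjusted p = 0.073 with an estimated correlation), H4C8 by 3.57-fold and H2AC6 by 2.28-fold. That median was 0.48 with 1 member not detected in EX527 at its bound, 0.40 or 0.41 with a larger offset, no background correction or the authors' values, and 1.11 with probes averaged. NF-kappaB and inflammatory genes were lower in 9 of 14, with a median of -0.20 (adjusted p = 0.013, and adjusted p = 0.073 with an estimated correlation). CCL2 was 4.66-fold lower, CXCL8 4.08-fold and the interleukin gene IL1B 2.1-fold, and TNFAIP3 (0.25) was higher. The median of the NF-kappaB and inflammatory genes was -0.31 with median scaling, -0.35 with no scaling and -0.13 with no filter on detection. With a stricter detection filter the histone and NF-kappaB lists lost their call (adjusted p of up to 0.056 in each). The histone list was not called against control in either compound (camera adjusted p = 0.21 in MC2494 and 0.3 in EX527). Genes of cytosolic ribosomal proteins were higher in 17 of 29, with a median of 0.21, or 0.11 with no scaling (adjusted p = 0.013, and adjusted p = 0.079 with an estimated correlation), and RPS7 was 2.94-fold lower.

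The amino acid response list did not differ as a whole between the compounds by the test (median 0.04, camera adjusted p = 0.53), with 10 of 25 genes higher in MC2494 and 9 lower. TRIB3 was 2.2-fold higher and PCK2 was 2.03-fold lower. Of 18 monocyte and macrophage genes 7 were higher in MC2494 and 7 lower (camera adjusted p = 0.83). The integrin ITGAM was 2.92-fold higher in MC2494, the Fc receptor FCGR1A 2.94-fold higher and the scavenger receptor CD36 4.48-fold lower. CEBPE, a transcription factor of granulocyte maturation, was 3.5-fold higher. SIRT2 was 2.05-fold higher in MC2494, SIRT4 1.71-fold, SIRT5 1.38-fold (0.96 and 0.48 on the log2 scale on other probes) and SIRT1 1.35-fold, and SIRT6 differed by -0.16 ± 0.10 (limma adjusted p = 0.16). Without MC2494 replicate 2, SIRT6 passed at -0.24 (adjusted p = 0.043). The sirtuin list was not called (camera adjusted p = 0.086).

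Between the compounds 6168 of 9956 genes differed (limma), 3292 higher in MC2494 and 2876 lower, with 643 at least 2-fold apart (279 higher and 364 lower) with undetected genes at their bound. The groups did not overlap for 55.5% of genes, against 2.86% by chance. The share of higher genes, 53.4%, was 41.9% with median scaling and 35.9% with no scaling between arrays, where the median of all genes moved from 0.021 to -0.095 on the log2 scale. Counts adjusted over the list alone equalled those over all genes for the lists called, except interferon-stimulated genes (15 against 13).

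**Figure D4:**
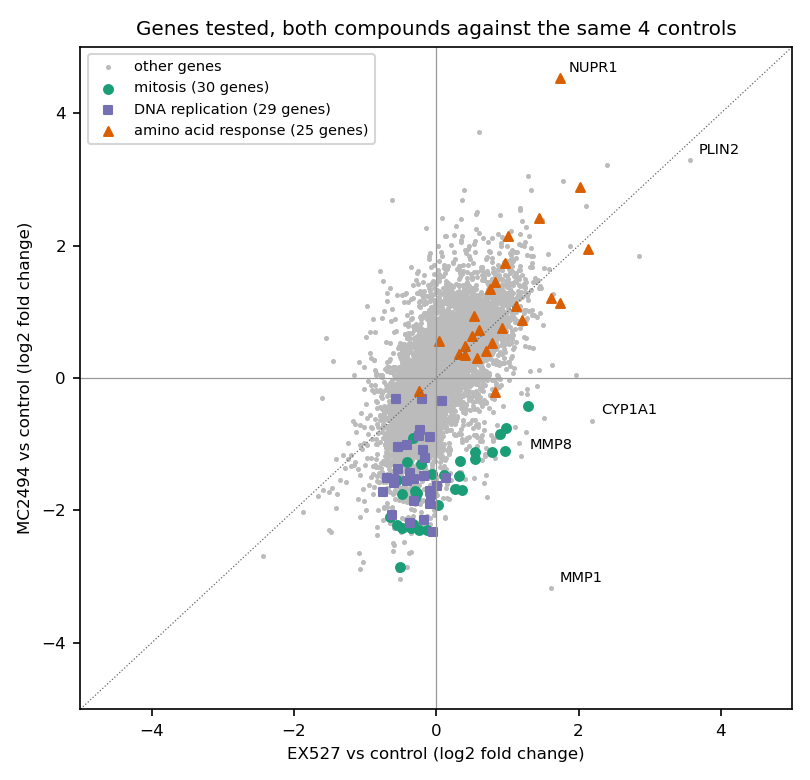
Log2 fold change against the same 4 control arrays of each gene tested, EX527 on the horizontal and MC2494 on the vertical axis, with 3 gene lists in colour and a dotted line of equal change. Of 25 amino acid response genes 23 lie to the upper right, mitosis genes lie below 0 for MC2494 and on both sides of 0 for EX527, and MMP1 (1.62 and -3.17) lies to the lower right; MMP8 and CYP1A1, not detected on any MC2494 array, are drawn at fitted values.

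Both compounds changed many of the same genes. Against control 2007 genes were higher in both and 2151 lower in both. Another 365 were higher in MC2494 and lower in EX527 and 212 the other way. Both comparisons use the same 4 control arrays, whose error by itself favours the same direction. With a separate pair of control arrays for each compound, over the 6 ways to form them, 1675 to 1734 genes were higher in both, where independent lists would share 768 to 813, and 1692 to 1778 were lower in both, where they would share 809 to 873. In opposite directions 246 to 316 genes were higher in MC2494 and lower in EX527 (independent lists, 870 to 950) and 162 to 187 the other way (713 to 748). The separate pairs take out only the error of single control arrays. An offset common to all 4 control arrays would stay in both pairs and was not tested. Genes are not independent of each other, so no p is given. Of the 4158 genes with the same direction, 2217 changed more in MC2494 and 361 more in EX527 with the difference itself called. With undetected genes at their bound, the collagenase gene MMP1 was the 1 gene that moved at least 2-fold in opposite directions with the difference called, 1.62 ± 0.10 higher in EX527 and -3.17 ± 0.10 lower in MC2494. MMP8 was 2.29-fold higher in EX527 and, not detected on any MC2494 array, at least 1.5-fold lower there.

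Across genes, which are not independent replicates, the log2 fold changes of the compounds correlated at r = 0.622. Simulated groups without effect that share the controls gave a mean of 0.5. That is the correlation of noise alone, and not the part of 0.622 that the shared controls bring, whose size the covariance shows. Splitting the controls so that each compound had its own 2 arrays gave 0.579 to 0.607. The covariance was 0.166, against 0.00353 in the simulations, a difference of 0.163, and 0.16 to 0.163 with split controls.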

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

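The check for an array far from the other 3 of its group was fixed beforehand and run on 567 groups of 4 values, for the genes named by the rule and for mean signal and detected probes. It picked out 25 groups, where chance alone picks out about 1 in 20, or 28. No array measure was among them. Values are normalized log2 signals. No explanation was tested for these single values.

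On control array 1, GCLM was 6.75 against 7.09 to 7.16 on the other 3 control arrays, and RBL1 was 7.74 against 7.88 to 7.9. BIRC2 was 9.2 there against 9.05 to 9.06, and TOP2A was 11.48 against 11.39 to 11.4. On control array 3, AQP8 was 4.81 against 5.07 to 5.09, all of them signals not detected above background. On control array 4, FABP4 was 5.01 against 4.58 to 4.62, also not detected, and TFEB was 6.45 against 6.21 to 6.24. ATG7 was 10.91 there against 10.75 to 10.76, and FANCG was 10.07 against 9.86 to 9.9.

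On EX527 array 1, SESN2 was 6.39 against 6.57 to 6.59 on the others, and on EX527 array 2, MKI67 was 7.44 against 7.62 to 7.65. EX527 array 3 had LAMP2 at 12.31 against 12.16 to 12.18, MT1G at 11.89 against 11.97 to 11.98, NOP16 at 9.4 against 9.68 to 9.72 and TK1 at 9.82 against 9.89 to 9.9. EX527 array 4 had the most, 5, with AZU1 at 10.13 against 10.24 to 10.25 and GCLM at 7.6 against 7.8 to 7.83. The others on that array were MMP9 at 5.36 against 4.93 to 4.99, NDRG1 at 9.21 against 9.11 to 9.12 and VEGFA at 9.71 against 9.49 to 9.52. MMP9 was detected on 1 of the 4 EX527 arrays, so most of these MMP9 values are signals not detected above background.

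On MC2494 array 1, CSF1R was 9.37 against 9.27. MC2494 array 2 had CRELD2 at 11.28 against 11.03 to 11.04, EXO1 at 8.58 against 8.74 and GPR84 at 6.43 against 6.69 to 6.72. MC2494 array 4 had MMP9 at 4.65 against 4.82 to 4.83.

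Probes without a gene name, which the comparisons leave out, also changed. Of 1215 such probes above the detection filter, 397 were higher and 402 lower in MC2494 than in control, and 289 were higher and 290 lower in EX527 than in control (limma, adjusted over these probes). The largest rise in MC2494 was 2.76 on the log2 scale, for probe ILMN_2073235, and the largest fall was -3.76, for probe ILMN_2150856.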

How the results depend on the processing

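Chosen after seeing the data were the fits to replicates 1 and 2 or 3 and 4 alone, the block of these pairs, no scaling, and the counts of genes changed by both compounds with separate controls. A block of slide or scan date was not run, as the sources used here give neither. Counts of changed genes stayed within 1.5 times the reported ones under each alternative except a 1.5-fold minimum, which left 3258 genes for MC2494 against control, 1205 for EX527 against control and 1949 for MC2494 against EX527, fewer by construction. Lists called fell from 8 to 5 for MC2494 against control with the estimated correlation, with median scaling and with no scaling. They fell from 8 to 4 for MC2494 against EX527 with the estimated correlation. The cause of these losses was not tested. A higher correlation between genes does not account for all of them. The histone list had an estimated correlation of -0.027, below the preset 0.01, and still went from an adjusted p of 0.016 to 0.073 (camera, MC2494 against EX527). No called list turned direction in the 26 alternatives recomputed per list. The correlation between compounds, 0.622, moved by more than its jackknife error of 0.0092 with split controls (0.579, 0.606, 0.589, 0.604, 0.593 and 0.607, fewer controls each), with median scaling (0.644), with no scaling (0.644) and in replicates 1 and 2 alone (0.609), the cause not tested for the scalings.

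Without each array in turn the correlation was 0.617 to 0.627. Of 292 named results 285 kept side and direction without each array. SIRT2 in EX527 against control, not past the threshold, turned from 0.04 to -0.02 in replicates 1 and 2 alone and ranged from 0 to 0.08 with each array left out, the lowest without control replicate 4, the cause not tested. With a replicate block 7275, 5737 and 6235 genes and 8, 4 and 8 lists were called for MC2494 against control, EX527 against control and MC2494 against EX527. The numbers did not pair the arrays: same-numbered arrays correlated at -0.04 to 0.19, and 2 of 12 correlated best with their own number. Signals near background limit the dim genes: folds are bounds for genes not detected on any array of the dimmer group, and remain fitted values for those detected on some of its arrays.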

Other observations

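Of the tests in this part, the one on replicates 1 and 2 against 3 and 4, the fits within these pairs, the fits with no scaling, the kinds of split and the lists of PPAR and aryl hydrocarbon receptor targets were chosen after the data had been seen, the lists before their other members were read.

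Immediate early genes, which respond to stimuli within minutes, had no common direction in MC2494: 7 of 14 rose and 6 fell (camera adjusted p = 0.63). KLF4 was 3.22-fold and KLF2 2.77-fold higher, and FOSB was 2.72-fold lower. In EX527, KLF2 was 1.68-fold lower, and KLF2 was 4.64-fold higher in MC2494 than in EX527. Cholesterol genes were not called in either compound, with a median of -0.03 and a mean of 0.12 in MC2494 (camera adjusted p = 0.92), yet SC5D, a late enzyme of cholesterol synthesis, was 4.64-fold higher in MC2494 and 2.08-fold higher in EX527, and INSIG1, which restrains that pathway, was 3.3-fold and 1.58-fold lower. Of endoplasmic reticulum chaperone genes in MC2494, 5 rose and 7 fell (adjusted p = 0.63), with DNAJB9 at 2.33-fold higher and SDF2L1 at 2.47-fold lower. Among autophagy and lysosome genes 10 of 18 rose in MC2494 and 3 fell (adjusted p = 0.14), with GABARAPL1 at 2.87-fold higher and ATG7 at 2.33-fold lower. VEGFA, a hypoxia target, was 3.41-fold higher in MC2494 and 2.1-fold higher in EX527, in a list of glycolysis and hypoxia genes of which 15 of 27 fell in MC2494 (adjusted p = 0.28).

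PLIN2, FABP4, CREB3L3 and CD36, seen to be high in EX527, are targets of PPAR receptors, so the hypothesis was tested that PPAR targets rose there as a group. Of 24 other measured targets 14 were higher and 4 lower in EX527 (limma), with a median log2 change of 0.24, at percentile 99.8 of 10000 random lists matched on expression, and 99.7 without VLDLR, which is also an amino acid response gene. ACADVL (1.32), ECH1 (0.96) and SLC25A20 (0.87), all of fatty acid oxidation, rose most. TXNIP (-0.45), PEX11A (-0.43), HILPDA (-0.4) and CPT2 (-0.15) fell. ANGPTL4, ACSL1, ECI2, UCP2, UCP3 and NR1H3 did not pass the test. The rise therefore did not rest on the 4 genes seen first, and higher PPAR activity may be a candidate explanation, which no value here tests directly. In MC2494 the same 24 genes had 12 higher, 7 lower, a median of 0.21 and percentile 89.3. That median is close to the 0.24 of EX527. The random medians spread more widely in MC2494, most of them from -0.26 to 0.33, than in EX527 (-0.19 to 0.14). The lower percentile in MC2494 therefore does not show a rise particular to EX527. Genes of a pathway can vary together, which random lists do not carry, so these percentiles are no p-values. Of the 4 genes seen first, PLIN2 and CREB3L3 were higher in MC2494, CD36 was lower (-1.46) and FABP4 (0.05) did not pass the test. PPARG itself, looked up afterwards, was higher by 2.13 in MC2494 and 0.92 in EX527.

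For CYP1A1 in EX527 the hypothesis was that targets of the aryl hydrocarbon receptor rose together. The 5 other measured targets had a median of 0.48, at percentile 99.2 of matched random lists, with TIPARP (0.96), NFE2L2 (0.75) and NQO1 (0.48) higher and LTB4R (-0.79) and CYP2S1 (-0.34) lower. Receptor activity may thus be one explanation, resting on 3 of 5 genes, of which NQO1 is also an NRF2 target. In MC2494 the 5 genes had a median of 0.52 (percentile 94.7) while CYP1A1, not detected on any MC2494 array, was at least 1.32-fold lower than in control. The median of these genes therefore did not follow CYP1A1 across the compounds.

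The fall of mitosis and DNA replication genes in MC2494 was set against technical explanations. The lower overall signal of the MC2494 arrays is argued against by the percentile of the list medians among 10000 random lists matched on expression, which was 0 for each list. With no scaling between arrays the list medians were -1.70 or lower in both lists, and the median of all genes was -0.079. These values argue against quantile normalization, and against a signal lower on all genes alike. Within replicates 1 and 2 and within 3 and 4 the medians were -1.51 or lower, which decides nothing about a difference between these pairs, since each group holds both. An effect of the compound on cell division stays open as a hypothesis, and cell counts or cycle phases were not analysed here.

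For the higher ribosomal protein genes in MC2494, the list median was 0.28 in one replicate pair and 0.29 in the other, which decides nothing about a difference between the pairs, since each group holds both. The scaling stays open, because the call ended with median scaling and with no scaling, where the list median fell to as low as 0.09 and 5 lists were called in place of 8.

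Within each group, replicates 1 and 2 lay on one side and 3 and 4 on the other side of the leading component of the spread within groups, which held 22.34% of it. The sides were close in EX527, with array 1 at -0.045 and array 3 at 0.013. The difference between the pairs, gene by gene, correlated between groups at 0.12 to 0.26. The pairs were chosen from that component, taken over all 3 groups, which by itself favours such a correlation. Whether 1 technical difference common to the 3 groups explains it therefore stays open. The labels name no batch, and no biological explanation was tested. Of 9956 genes 12 differed between the pairs, a count that the choice of pairs from the same values also favours. Within replicates 1 and 2 alone 6334, 4053 and 5053 genes were called, and within 3 and 4 alone 6500, 4461 and 5144, for MC2494 against control, EX527 against control and MC2494 against EX527.

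Each comparison was set against the 35 splits of its 8 arrays into 4 and 4. For the counts of changed genes, 1 of 35 splits in each comparison, the real one, gave as many. It gave 7222, 5656 and 6168 genes against at most 0 in the others (limma). The other splits mix the groups compared, which widens the spread within each side, so with differences this large a low count there was set in advance. Nor can the splits speak to chance between cultures, since the arrays may be repeats of the same culture. For the number of lists called chance is not excluded by this count, since 4 of 35 splits gave at least the 8 lists of MC2494 against control (highest other 9), 12 of 35 at least the 4 of EX527 against control (highest other 6) and 5 of 35 at least the 8 of MC2494 against EX527 (highest other 9). The other splits that gave as many all kept 3 arrays of a group against 1, and the 18 splits with 2 arrays of each group on a side called at most 0, 1 and 1 lists. Splits of 3 against 1 keep part of the real difference between the groups. Their list counts are therefore no measure of chance, and the count of lists over splits cannot decide the question. The split of replicates 1 and 2 against 3 and 4 called 0 lists in each comparison.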
